A study of Mus musculus with 107 samples.

How the data were processed

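The series holds 107 Agilent arrays of 2 colours, each comparing RNA of FE1 mouse lung epithelial cells with a common mouse reference RNA. Per the labels, the cell sample carried Cy5 and the reference Cy3 on every array, with no swap of the dyes, and RNA with an integrity number of at least 5 was used. The arrays form 32 groups: copper oxide nanoparticles (NP) or microparticles (MP) at 1, 5, 10 and 25 µg/mL, CuCl2 at 7 µg/mL, NaCl at 5 µg/mL and plain medium, at 2, 24 and 48 h. Of these, 28 groups hold 3 arrays and MP 25 at 24 h holds 2. Medium holds 7 at each time: set A (4, on slides with particle samples) and set B (3, on slides with salt samples). At 2 h, NaCl replicate 1 and CuCl2 replicate 2 lay on particle slides. Both sets carry the same titles, and the labels do not say whether they are separate cultures (r -0.07 to 0.71 between same titles). At 48 h the Hmox1 log2 ratio was -2.98 and -3.01 in replicate 1 of both, and 0.4 to 0.67 in other medium. NP 25 at 48 h is not analysed here.

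Per the file headers, the scanner files were made with Agilent Feature Extraction 11.0.1.1 and hold, for each of 62976 spots, deposited median intensity values and local background in each colour, with the software's background-corrected, dye-normalized processed signal. The design had planned to use mean intensity values, which the files do not carry, so the median intensity was used. The deposited series matrix was read as log2 ratios of sample over reference. Apart from 1 dim array, described below, its columns correlated with log2 ratios computed from the scanner files (r 0.979 to 0.993, slope 0.973 to 1.06), and their medians were 0.002 to 0.031. How the submitters normalized the matrix is not given in the sources used here.

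Of the spots, 59305 are not controls, and they measure 56605 probes. The files carry no column of gene names, so each probe's RefSeq accession was matched to a reference list of the GRCm38.p6 assembly. The match named 33767 probes of 23462 genes, and the 22838 other probes were left out of the main tests. No coordinates are given, because the files use another build.

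Signals were background-corrected with limma's normexp (offset 50) and normalized within each array by loess. Spots set aside by the scanner software were treated as missing, which removed 0.15% of the tested values. A probe was kept when its red signal was well above background on every array of at least 1 group, which left 20387 named probes. For the 5140 genes with more than 1 such probe, the brightest was used, giving 13866 genes. The tools were R 4.3.3, limma 3.58.1, data.table (version 1.17.8) and statmod 1.5.0.

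Across the other 106 arrays, 42.1 to 53.5% of probes were above background in red and 48.8 to 60.4% in green, and 0.16 to 0.52% of spots had been set aside by the software. The median red signal net of background was 16 to 50 units, and 0 or 1 spot per array was saturated. In the dim array, replicate 1 of NP 25 at 24 h, 29.3% of probes were above background in red and 25.9% in green, 9.19% of spots had been set aside, and r with the series matrix was 0.479. It stayed in the main fit. The number of arrays per group limits the precision, and p values between replicates measure only the spread between these samples.

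A linear model with 1 mean per group, with medium split by set, was fitted to all arrays with limma (72 residual degrees of freedom, 4.9 prior). The 49 comparisons were each particle dose against medium of set A, CuCl2 and NaCl against medium of set B, CuCl2 against NaCl, NP against MP at each matched dose, and the CuCl2 effect minus the NP 5 or NP 10 effect. The salt's 7 µg/mL is mass of compound, not matched in copper. Benjamini-Hochberg adjustment ran within each comparison. A gene was called when its adjusted p was under 0.05 and its fold at least 1.5. These choices, the gene lists and the alternatives were written before the data were examined. Log2 fold changes are given with their standard errors (SE) from this fit, and padj beside a gene is limma's adjusted p.

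Lists of genes written before the data were examined were tested in 12 key comparisons with limma's camera at a preset correlation of 0.01, adjusted over 300 tests. The 20 gene lists cover metal response, copper transport, NRF2 targets, cytosolic heat shock, the integrated stress response, ER chaperones, p53 targets, mitosis, DNA replication, inflammatory cytokines, immediate early genes, cholesterol synthesis, glycolysis and hypoxia, extracellular matrix, oxidative phosphorylation, lipoylation and iron-sulfur genes, iron handling, proteasome, lysosome and ribosomal proteins. The 7 marker lists cover epithelial cells, alveolar type 2, alveolar type 1, club and ciliated cells, fibroblasts, leukocytes and endothelial cells, and the 25 lists with at least 3 measured members could be tested. Each test was repeated with the correlation estimated from the residuals, with fry, and with the replicate block. Members were also counted after adjusting their p values over the list alone.

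In each key comparison the named genes are the 6 largest called rises and 6 largest called falls, and up to 4 called members of each list, largest change first. Mt1, Mt2, Slc30a1 and Hmox1 were always named. Some genes that the rule selects are not reported here. For the CuCl2 effect minus the NP 10 effect the 3 largest differences were named. Genes named in a comparison with few calls outside the key ones were chosen after their values were seen, as were the dose series of genes the rule had named.

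Alternatives to the main fit were: no background correction, the scanner's processed signals, scaling between arrays after loess, the series matrix, no filter on dim probes, a filter for signal above background on at least 50% of all arrays, the mean of a gene's probes, slide as a fixed or random block, all medium arrays of a time together, the replicate number as a block, the arrays of that time alone, array weights, adjusted p without the fold threshold, and leaving out each array in turn. After the data were examined, 4 more were added: the dim array left out, the dim array and replicate 1 of MP 10 at 48 h left out, medium arrays with the same title averaged over the sets, and the replicate block within each time. The overlap of NP doses with the medium arrays divided between them and the reassignment of labels within replicate numbers were also added then.

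The labels do not say what a replicate number shares. In all 9 salt comparisons, samples with the same number deviated together from their group means (r 0.21 to 0.66 over 3 pairs each), and likewise in the 4 comparisons of NP with MP at 2 h (r 0.29 to 0.6). Blocked counts are given beside a total or salt comparison where they move it by more than 1.5 times.

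The pipeline was tested on simulated data: 50 genes each were changed by 1.5, 2, 3 or 4-fold among the 13866. For NP 10 at 48 h it recovered 38, 96, 100 and 98% of them with 6 false calls, for CuCl2 at 48 h 38, 100, 100 and 100% with 7, and for MP 25 at 24 h 48, 90, 96 and 98% with 4. Group labels were also reassigned within sets of arrays in every way, or in 100 random ways where several doses were pooled. The pooled counts were also set against labels reassigned among arrays of the same number. Signs within slides were counted for called genes on the arrays that gave the calls, so they speak to the slide alone and add no separate evidence for a gene.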

Results

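Gene expression was measured in FE1 mouse lung epithelial cells exposed to copper oxide as nanoparticles (NP) or microparticles (MP), or to dissolved copper as CuCl2, with NaCl as the chloride control. The question was how far particle size, and copper already in solution, set the response over dose and time. There were 107 arrays in 32 groups, with 3 arrays in 28 of them, 2 in MP 25 at 24 h, and 7 of medium at each time. Between 42.1 and 53.5% of probes were above background in the sample colour on 106 arrays, and 29.3% on the remaining one, replicate 1 of NP 25 at 24 h. Changes are log2 fold changes ± SE, and padj is the adjusted p from limma or, for lists, camera. Particles were compared with the 4 medium arrays of set A and salts with the 3 of set B, and a gene that rose or fell passed both thresholds. At 2 h, replicate 1 of NaCl and replicate 2 of CuCl2 lay on particle slides, apart from medium of set B. Over 11720 genes, the first principal component held 60% of the variance and the second 14.8%.

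The nanoparticles raised the metal-binding Mt2 at 24 h from the lowest dose up, and the heat shock gene Hspa1a from 5 µg/mL, while Mt2 was not called for the microparticles or CuCl2 at that time. Hspa1a at MP 25 stood at 2.32 (2 arrays), uncalled over all arrays (padj = 1) and called without the dim array (padj = 0.027). At 24 h the NP doses 1, 5, 10 and 25 raised 1, 197, 892 and 2087 genes and lowered 0, 42, 779 and 2006. At 48 h the doses 1, 5 and 10 raised 18, 1522 and 2985 and lowered 15, 1255 and 2726, so that NP 10 moved 41.2% of the tested genes. Over any dose, NP changed 18, 4420 and 5825 genes at 2, 24 and 48 h, and MP changed 48, 4 and 19. Of 100 assignments of the group labels, the real one included, 8 gave at least as many NP genes at 2 h (highest 126), and only the real one did at 24 and 48 h (next 3526 and 5024). For MP they were 3 at 2 h (highest 201), 1 at 24 h (next 1) and 7 at 48 h (highest 100).

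**Figure D1:**
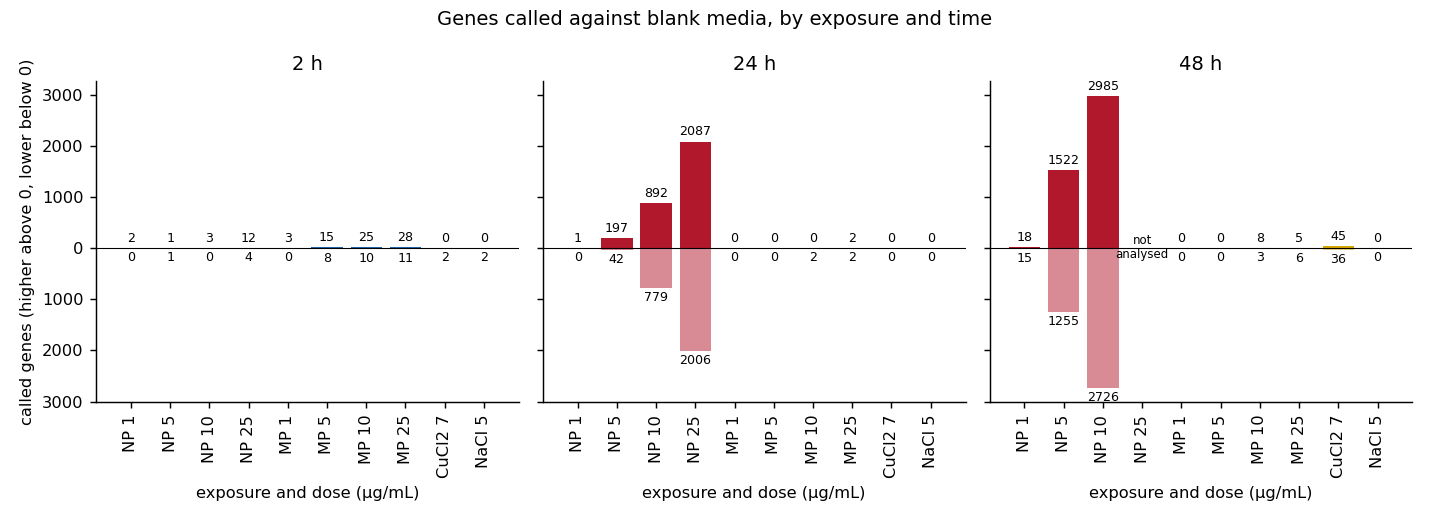
Number of genes that rose (upward) or fell (downward) against medium for each treatment, dose and time. Each bar is 1 comparison.

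NP 25 at 2 h raised Mt1, which encodes a metallothionein that binds excess metal, by 1.57 ± 0.35 (2.96-fold, padj = 0.032, 3 arrays against 4). Its partner Mt2 stood at 1.12 ± 0.27 (padj = 0.05) without being called. The lysosomal peptidase gene Dpp7 rose by 1.24 ± 0.28 (padj = 0.035) and the lysosomal protective protein gene Ctsa by 0.86 (padj = 0.049). So did Lgals3bp, a secreted galectin-binding protein (1.23, padj = 0.032), Wdr92 (1.19), the interleukin 6 receptor Il6ra (0.8) and the early nuclear receptor Nr4a1 (0.79, padj = 0.035). The cyclin F gene Ccnf fell by 0.91, the ubiquitin-conjugating Ube2c by 0.79 (padj = 0.038), the helicase gene Pif1 by 0.77 (padj = 0.027) and the kinesin Kif18b by 0.62. The haem-degrading Hmox1 was at 0.77 (padj = 0.84) and the zinc exporter Slc30a1 at 0.14 (padj = 0.95). In all, 12 genes rose and 4 fell (1177 at unadjusted p under 0.05), and 55 were called without the dim array. All 16 had the same sign within each of the 2 slides that held both groups. Scaling between arrays gave 32 rises and 5 falls (86.5% higher against 75), and the series matrix 5 and 3. The lower doses called few genes, named here after their values were seen. At 1 µg/mL the chemokine gene Ccl20 (1.32, padj = 0.016) and Tiparp, a target of the aryl hydrocarbon receptor (0.77, padj = 0.013), rose. At 5 µg/mL Tiparp rose (0.74, padj = 0.021) and Arhgef39 fell by 0.59 (padj = 0.024). At 10 µg/mL Ccl20 (1.42, padj = 0.0032), Lgals3bp (1.38, padj = 0.011) and Pbxip1 (0.62, padj = 0.026) rose.

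As groups at NP 25 and 2 h, 1 of 32 lysosome genes rose (8 with p adjusted over the list alone), with a median of 0.42 (camera padj = 8.6e-12, adjusted p = 0.08 with an estimated correlation). With the replicate block that second value was 0.0088. Of 30 mitosis genes 1 fell (4 over the list alone), median -0.36 (padj = 1.2e-13, adjusted p = 0.23 with an estimated correlation). In the metal response list 1 of 12 rose (2 over the list alone), median 0.17 (padj = 0.0081, 0.12 with an estimated correlation and 0.05 in that test with the replicate block). The p53 targets had a median of -0.14 with no called member (padj = 0.002), and kept their call with an estimated correlation (padj = 0.036), though at 0.055 without the dim array. Matrix genes (median 0.22, padj = 0.00077, adjusted p = 0.36 with an estimated correlation), inflammatory genes (0.13, padj = 0.016, then 0.36) and immediate early genes (0.14, padj = 0.021, then 0.64) had 1, 1 and 3 members called over the list alone. The NP total of 18 depended on single arrays. It was 2, 5 and 3 without medium replicate 1, 2 or 4 of set A, and 6 without replicate 3 of NP 25. It was 28 without replicate 1 of NP 10, 34 and 48 without replicates 3 and 4 of NP 1, and 62 without the dim array, which belongs to another time but enters the variance of the fit. With slide as a fixed block it was 28, and with the replicate block 61.

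At 24 h NP 10 raised Mt2 by 3.16 and Mt1 by 3.07 (3 arrays against 4), and the doses 1 and 5 raised Mt2 by 1.39 (padj = 0.039) and 2.94. Slc30a1, which exports zinc and is driven by the same metal sensor as the metallothioneins, rose at 5 (0.61, padj = 0.014) and 10 µg/mL (0.67, padj = 0.00064). Hmox1 stood at 0.72 at 1 µg/mL and rose by 2.85 (padj = 0.00092), 4.32 (padj = 1e-08) and 3.74 (padj = 8.1e-08) at 5, 10 and 25. Hspa1a, an inducible chaperone, stood at 0.45, 4.96, 7.17 and 5.7, and Srxn1, which repairs oxidized peroxiredoxins, at 0.22, 1.35, 2.49 and 1.91. The lower values at 25 than at 10 rest on the dim array: without it NP 25 gave 5.51 for Hmox1, 8.02 for Hspa1a and 3.2 for Srxn1. The collagen gene Col3a1 stood lower at each dose (-0.19, -0.62, -1.64 and -3.41). Every gene that NP 5 lowered (42) and 185 of the 197 it raised were called in the same direction by NP 10. NP 10 and NP 25 shared 751 rises and 602 falls with 1 gene opposite. These comparisons share the 4 medium arrays. With those divided between the doses in 6 ways, NP 10 called 82.6 to 98.5% of the rises and 88.5 to 100% of the falls of NP 5, and NP 25 called 77.2 to 85.6% and 68.6 to 80.7% of those of NP 10. The 239 genes of NP 5 and the 1671 of NP 10 kept their sign within each slide that held both groups.

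NP 25 at 24 h raised Hspa1a by 5.7 ± 0.66 (51.9-fold, padj = 1.1e-11, 3 arrays against 4). Its pair Hspa1b rose by 5.26, Arc, an activity-regulated cytoskeletal gene, by 5.27, the phosphatase gene Dusp2 by 4.8, Tex19.1 by 4.76 and the membrane protein gene Tmem171 by 4.84 (2 arrays with a value). Mt2 rose by 3.15 ± 0.31 (padj = 3.2e-14), Mt1 by 2.46 (padj = 7.4e-09), the metal sensor Mtf1 by 1.29 and the copper transporter Slc31a2 by 0.73, while the zinc importer Slc39a10 fell by 3.16. The largest falls were Spats2l (-3.76), the membrane proteins Lrrn4 (-3.66) and Gpm6a (-3.35), the pattern receptor Ptx3 (-3.56), Col3a1 (-3.41) and the alarmin Il33 (-3.32). Division genes fell, led by the kinase Plk1 (-2.85 ± 0.18, padj = 2.5e-23), the kinetochore motor Cenpe (-2.76), the centromere histone Cenpa (-2.51) and Kif20a (-2.49). Early transcription factors and their regulators rose: Egr1 (4.42), Dusp1 (4.21), Fosl1 (3.82) and Atf3 (3.09), as did the prostaglandin synthase Ptgs2 (3.12). In all 2087 genes rose and 2006 fell, and within each of the 2 slides that held both groups 96.3% of 4093 kept their sign.

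The dim array weakened some changes and deepened others. Without it 2407 genes rose and 2553 fell, with changes of 8.02 for Hspa1a, 7.46 for Hspa1b, 6.59 for Arc, 5.51 for Hmox1, 3.24 for Mt1 and 4.97 for Atf3. Slc30a1 went from 0.2 (padj = 0.28) to 0.85 (padj = 4.7e-13). Some calls rested on it: Spats2l went from -3.76 to -1.45, the keratin Krt19 from 2.72 to 0.11, the replication factor Cdc6 from -1.14 to -0.05 and Uhrf1 from -1.65 to -0.19. The oxygen sensor Egln3 turned from 1.31 to -0.24, the lactate exporter Slc16a3 from 1.27 to -0.1, and the endothelial marker Vwf went from 2.75 to 1.73. With the scanner's processed signals the all-gene median of this comparison shifted by -0.119 and 2148 genes rose against 3101 that fell, 40.9% against the 51% of the main fit.

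Of 37 NRF2 targets, which detoxify oxidants, 22 rose and none fell at NP 25 and 24 h (median 0.84, padj = 3.2e-09, adjusted p = 0.2 with an estimated correlation, and 0.031 without the dim array). Examples are Osgin1 (3.55), the biliverdin reductase Blvrb (2.6) and the autophagy adaptor Sqstm1 (2.41). Of 26 heat shock genes 17 rose and 1 fell (1.11, padj = 1.4e-07, then 0.31), among them Dnajb1 (2.99) and Hsph1 (2.81). Of 26 immediate early genes 22 rose and 1 fell (2.06, padj = 1e-13, then 0.063). Of 31 proteasome subunits 17 rose, and 28 without the dim array (0.67, padj = 7.2e-08, adjusted p = 0.36 with an estimated correlation), such as Psma1 (1.75), Psmd3 (1.55), Psma5 (1.51) and Psmc6 (1.22). Of 32 lysosome genes 21 rose and 1 fell (1.07, padj = 6.1e-08, adjusted p = 0.2 with an estimated correlation, 0.045 in that test with the replicate block). Examples are the sialidase Neu1 (2.25), Ctsa (1.99) and the protease Ctsd (1.86). Of 30 mitosis genes 25 fell and 1 rose (-1.69, padj = 1.6e-11, then 0.29). Their list mean was -1.75 on the dim array, -1.15 and -1.07 on the others. Of 24 cholesterol genes 9 fell and 2 rose (-0.37, padj = 0.011, then 0.59), with Mvk (-1.46), Hmgcs1 (-1.36) and Idi1 (-1.09). Of 29 matrix genes 14 fell and 7 rose (-0.57, padj = 0.026, then 0.6), the inhibitor Timp3 by -3.24 against Ccn1 at 2.49. Without the dim array, camera no longer called cholesterol (padj = 0.066) or matrix (padj = 0.13).

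The remaining lists at NP 25 and 24 h went both ways. In the integrated stress response 7 of 30 rose and 12 fell (median 0.02, padj = 0.99), and without the dim array 10 rose and 7 fell (padj = 0.34). Ppp1r15a, which restarts translation, rose by 2.62 and Chac1 by 1.77, while the kinase-like Trib3 fell by 1.49 (-0.91 without the dim array). With the series matrix that median was -0.52. ER chaperones had 1 rise and 7 falls of 22 (-0.26, padj = 0.066), with Dnajb9 at 1.21, Herpud1 at -0.97 and Pdia6 at -0.89. Among p53 targets 9 of 30 rose and 8 fell (median -0.15, with the test pointing up, padj = 0.81), with Plk3 (2.26), Gdf15 (1.8), Gadd45a (1.42) and Fas (-1.64). DNA replication genes had 3 rises and 8 falls of 32 (-0.14, padj = 0.66), and 7 rises and 0 falls without the dim array. Inflammatory genes had 6 rises and 4 falls of 27 (0.2, padj = 0.63), with Mmp3 at 2.29. Glycolysis and hypoxia had 11 and 5 of 32 (0.34, padj = 0.074, and called without the dim array at padj = 0.013), with the hormone Adm at 2 and Ndrg1 at 1.23. In the metal list 4 of 12 rose and 2 fell (0.12, padj = 0.68), and in the copper list 1 of 20 rose and 3 fell (-0.17, padj = 0.73), with Steap2 at -0.68 and Lox at -0.67. Iron handling had 3 rises and 1 fall of 14, with the mitochondrial iron importer Slc25a37 (1.98), the ferritins Ftl1 (1.75) and Fth1 (1.05) and transferrin Trf (-1.51).

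At 48 h NP 10 raised Hspa1a by 8.46 ± 0.66 (353-fold, padj = 2.5e-19, 3 arrays against 4). It raised Arc by 7.22 ± 0.5 (149-fold), Hspa1b by 7.1 (137-fold), the natriuretic peptide gene Nppb by 6.32 (80.1-fold), Atf3 by 5.45 and Hmox1 by 5.13 ± 0.58 (35-fold, padj = 2.3e-12). Without medium replicate 1 of set A the rise of Hmox1 was 4.25 (19.1-fold). Large falls were those of Nrep (-5.29), the matrix proteoglycan Dcn (-5.03), Lrrn4 (-4.72), Smtnl2 (-4.67) and the cytokine Il18 (-4.67). Mt2 rose by 1.32 (padj = 1.8e-05) and Mt1 by 0.96 (padj = 0.012), less than at 24 h, and Slc30a1 stood at 0.5 (padj = 0.0044) under the fold threshold. Mtf1 rose by 1.38, the copper-zinc enzyme gene Sod1 by 1.07 and the selenoprotein Selenoh by 1.33, and the copper pump Atp7a fell by 0.71, the copper-dependent Lox by 1.42 and Slc39a10 by 2.81. The collagen genes Col3a1 (-3.9 ± 0.16, padj = 6.8e-35) and Col6a2 (-3.98) fell, and the matrix gene Ccn2 rose by 3.67. Division genes stood above medium (Tpx2 3.67, Birc5 3.32, Nuf2 2.95, Bub1 2.8), with replication and repair genes (Mcm10 3.06, Rrm2 3.04, Exo1 2.91). From 24 h the mitosis mean moved by -3.28 in medium and -0.82 in NP 10. In all 2985 genes rose and 2726 fell, and within the 2 slides that held both groups 5710 of 5711 and 5646 of 5705 kept their sign.

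Of 30 mitosis genes 28 rose and none fell at NP 10 and 48 h (median 1.81, padj = 2.6e-10, adjusted p = 0.32 with an estimated correlation), and of 32 DNA replication genes 30 rose (1.59, padj = 6.7e-10, adjusted p = 0.35 with an estimated correlation). Over the list, mitosis genes stood 1.79 above medium of 48 h and at -1.49 from medium of 24 h. Of 31 proteasome subunits 30 rose (1.45, padj = 3.7e-13, then 0.2), among them Psmb3 (2.17), Psmc4 (2.17), Psmd3 (2.01) and Psmd12 (1.92). The integrated stress response rose in 25 of 30 (1.52, padj = 2e-09, then 0.26): Ppp1r15a by 4.01, Cth by 2.65, Chac1 by 2.59 and Trib3 by 2.51. NRF2 targets had 28 rises and 2 falls of 37 (1.48, padj = 2.5e-09, then 0.2), with Srxn1 (3.7), Sqstm1 (3.68) and Osgin1 (3.6). Heat shock genes rose in 23 of 26 (1.42, padj = 1.4e-08, then 0.27), with Dnajb1 (4.4) and Hsp90aa1 (3.44). Immediate early genes rose in 24 of 26 (2.05, padj = 4.1e-10, then 0.16), with Fosl1 (4.44) and Maff (4.26). Of 29 matrix genes 18 fell and 9 rose (-0.84, padj = 0.0094, then 0.53). Of 32 glycolysis and hypoxia genes 15 rose and 3 fell (0.4, padj = 0.019, adjusted p = 0.36 with an estimated correlation), led by the glucose transporter Slc2a1 (2.14), the hexokinases Hk1 (1.85) and Hk2 (1.84) and Pfkp (1.76). For every list in this comparison the counts adjusted over the list alone were the same.

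The other lists were not called at NP 10 and 48 h. Lysosome genes had 12 rises and 4 falls of 32 (0.42, padj = 0.16), with Gabarapl2 (2.2) and Ctsd (1.35). Oxidative phosphorylation had 7 rises of 29 (0.07, padj = 0.2), with cytochrome c Cycs (1.36) and Uqcrc1 (0.66), and a median of -0.18 with the series matrix. Lipoylation and iron-sulfur genes had 4 rises and 3 falls of 22, with Fdxr (-1.64), Pdhb (1.09), Lipt2 (-0.88) and Dlst (0.84). Iron handling had 4 and 3 of 14 (median -0.1, with the test pointing up, padj = 0.8), with Trf (-3.59) against Tfrc (2.28) and Ftl1 (1.9). ER chaperones had 3 and 1 of 22 (median -0.07, test up, padj = 0.81), with Hspa5 (1.58), Dnajb9 (1.57), Syvn1 (1) and Dnajc3 (-0.69). Among p53 targets 8 rose and 10 fell of 30, with Gdf15 (4.07), Plk3 (3.62), Gadd45a (2.3) and Trp53inp1 (-2.09). Inflammatory genes had 5 rises and 4 falls of 27, with Ptgs2 (3.43), Ccl2 (1.53), Il1rl1 (1.41) and Il33 (-2.47). Cholesterol genes had 4 and 5 of 24 (-0.21), with Tm7sf2 (-1.17), Hmgcs1 (-1.09), Idi1 (-1.07) and Fdft1 (-1). The metal list had 4 and 1 of 12 (0.4, padj = 0.52), the copper list 1 and 2 of 20 (-0.16), and ribosomal proteins 1 fall of 30, Rpl3 (-0.68).

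Among cell type markers at NP 10 and 48 h, fibroblast genes fell in 4 of 9 and rose in 1 (median -0.54, padj = 0.1): Dcn, Pdgfra (-2.13) and S100a4 (-1.46) against Thy1 (1.08). Of 7 epithelial markers only the keratin Krt7 was called (-3.12). Of 4 alveolar type 2 markers Etv5 (3.24) and Lamp3 (1.59) rose and the surfactant lipid transporter Abca3 fell by 1.52. Of 7 alveolar type 1 markers Aqp5 (0.95) and Clic5 (0.79) rose and Hopx fell by 2.71. Medium arrays were not above background for Clic5 or Vwf, so their rises were at least 1.68-fold and 7.4-fold. Vwf was 1 of 2 endothelial markers, Tubb4b (2.26) was the 1 club and ciliated marker measured, and 0 of 5 leukocyte markers were called.

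**Figure D2:**
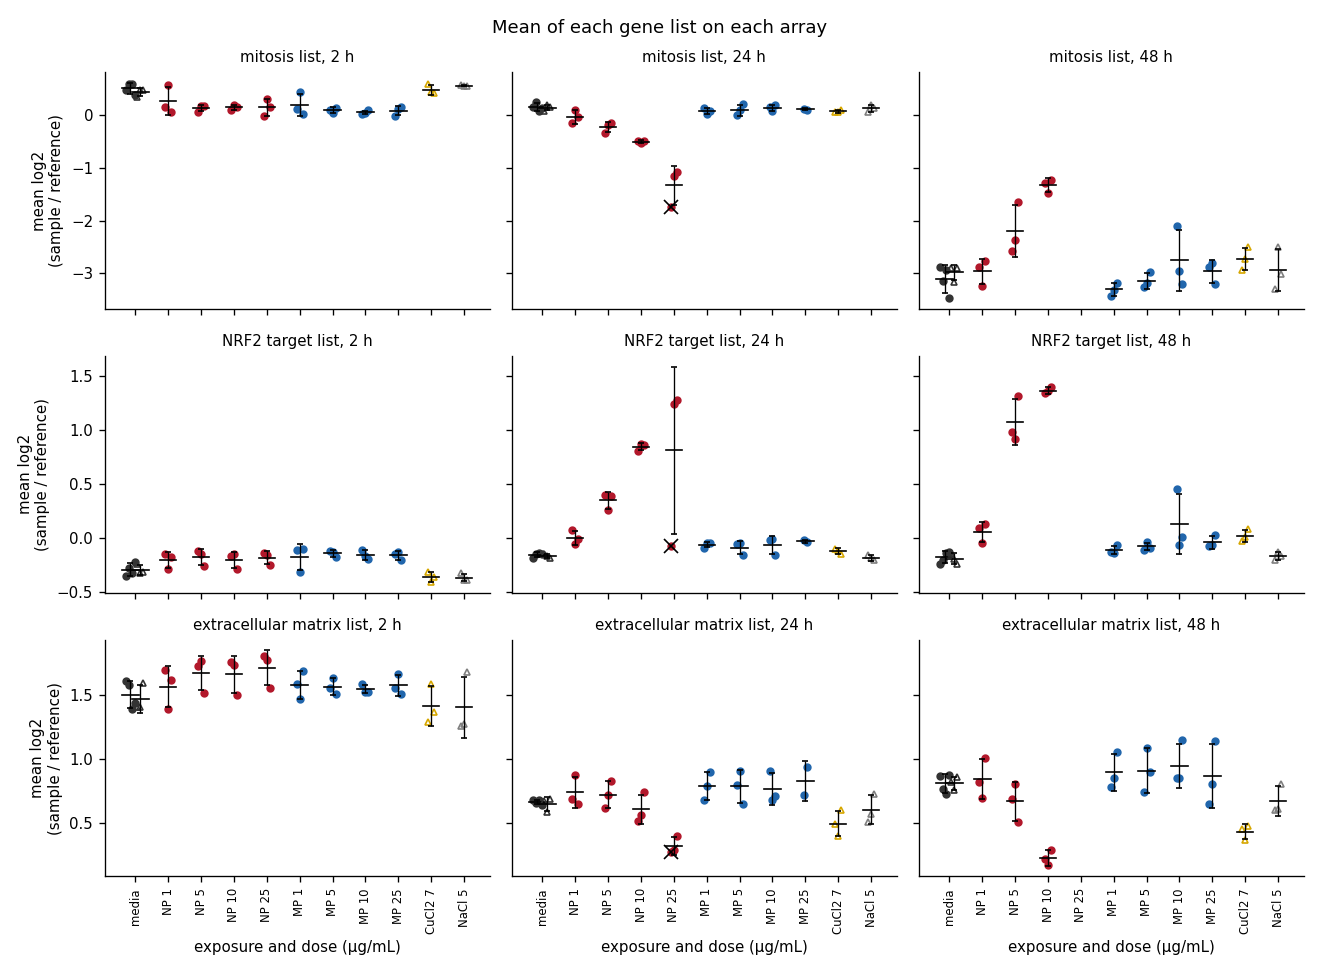
Mean log2 ratio of the mitosis, NRF2 and extracellular matrix lists on each array, by treatment and time. Filled circles are particle arrays and medium of set A, open triangles salt arrays and medium of set B, and the cross the dim array.

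Lower NP doses at 48 h moved many of these genes less. NP 5 raised Hspa1a by 7.8, Hmox1 by 5.05 (4.17 without medium replicate 1 of set A), Srxn1 by 3.26, Arc by 4.0 and the stress cofactor Nupr1 by 2.34, and changed Mt2 by 1.92 and Col3a1 by -2.27 (3 arrays against 4). Of its 1522 rises, 1449 were shared with NP 10, and of 1255 falls, 1212. With the 4 shared medium arrays divided between the doses, 92.7 to 94.8% of rises and 91.4 to 94.9% of falls were shared. At NP 5 all 28 called NRF2 targets rose (median 1.1), as did 22 in the integrated stress response (1), 28 proteasome subunits (0.97), 21 mitosis genes (0.8) and 16 of DNA replication (0.59). Without replicate 2 of NP 5 these were 20 proteasome subunits, 14 mitosis genes (0.53) and 8 of DNA replication (0.31). NP 1 raised Hspa1a by 2.69 (padj = 0.027), Fgfbp1 by 1.21 and Cyp1b1, which oxidizes aromatic compounds, by 1.14. It lowered the differentiation inhibitors Id1 (-0.77, padj = 9.7e-05) and Id2 (-1.14, padj = 0.0086), Angptl7 (-1.17) and the amine oxidase Aoc3 (-1.09). With scaling between arrays NP 1 had 20 rises and 25 falls (44.4% higher against 54.5), and with the series matrix 14 and 18 (43.8%). Its 33 genes were 59 without the dim array.

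The NP response changed with time. For NP 10, 1512 genes differed between the effects at 24 and 2 h (694 higher and 818 lower at 24 h). Between 48 and 24 h 3959 differed (1987 higher, 1972 lower), and 56 of them were called at both times in opposite directions. For NP 5, 1771 differed between 48 and 24 h (955 higher, 816 lower), and 20 of 30 genes in the integrated stress response had a higher effect at 48 h. NP 10 at 24 and 48 h shared 723 rises and 633 falls (192.03 and 153.15 by independence, separate medium arrays). At NP 5 and 10 Trib3 stood at 0.08 and -0.02 at 24 h and rose by 2.28 and 2.51 at 48 h, where its log2 ratio in medium was -1.52 against 1.39 at 24 h.

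**Figure D3:**
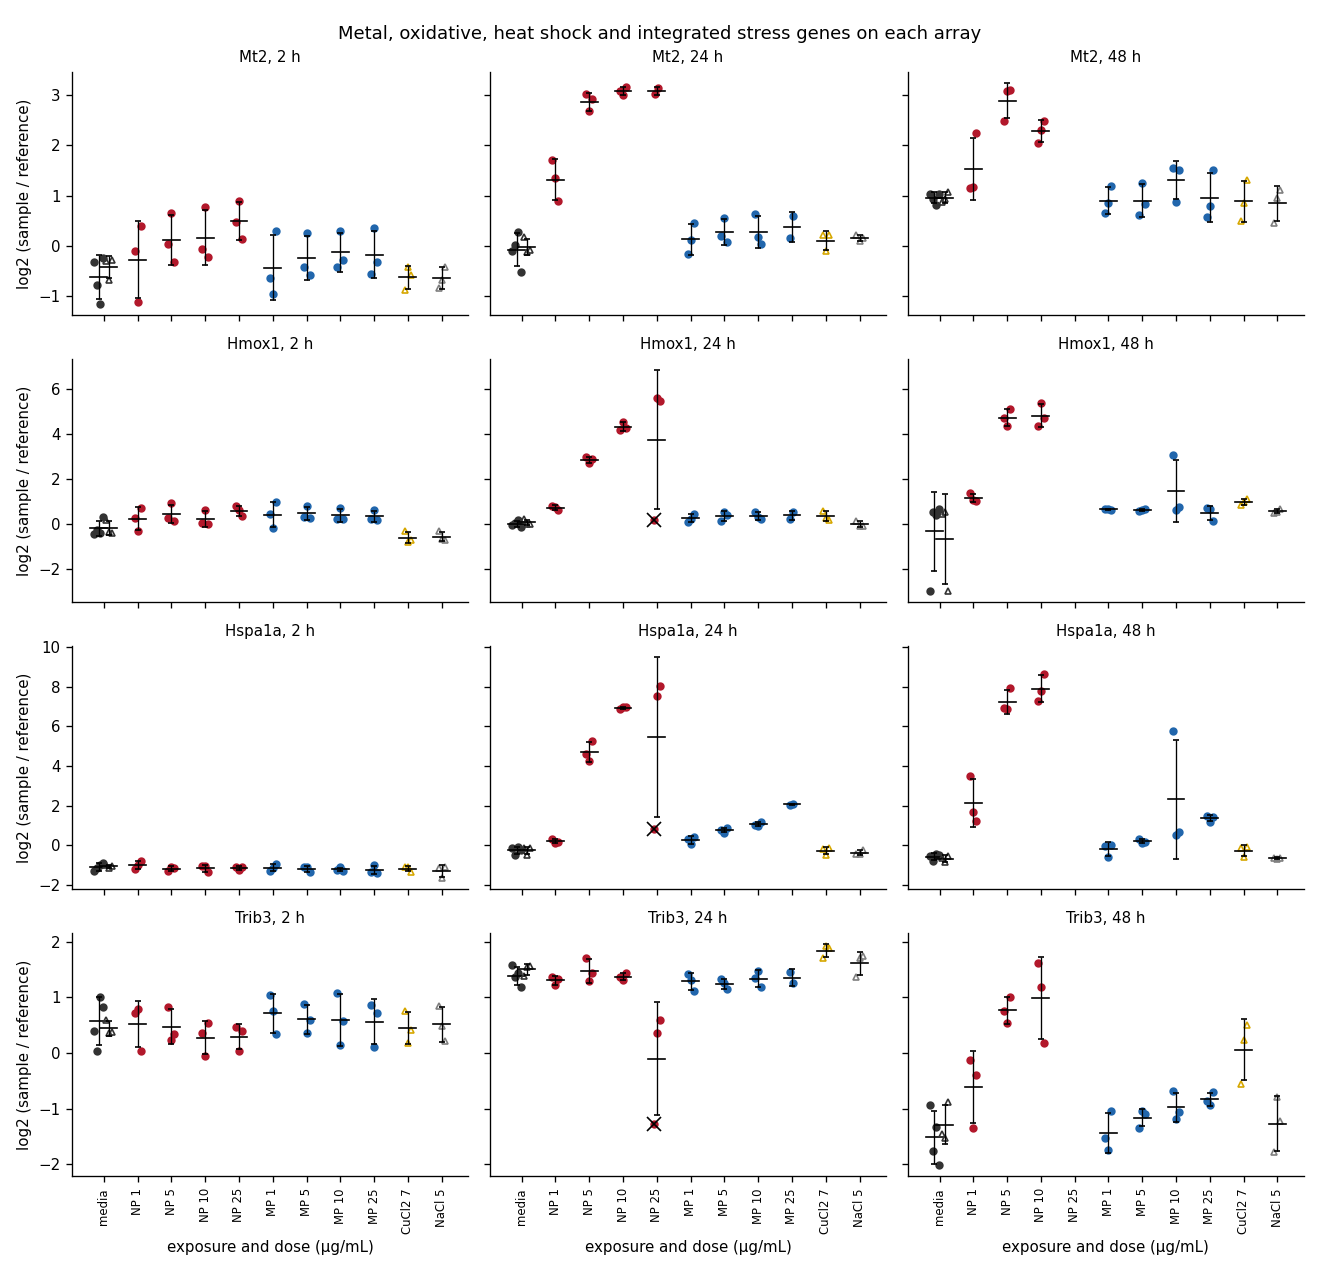
Log2 ratio of Mt2, Hmox1, Hspa1a and Trib3 to the reference on each array, by treatment and time. Bars are means ± SD, filled circles particle arrays and medium of set A, open triangles salt arrays and medium of set B, and the cross the dim array.

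MP 25 at 2 h raised Ccl20, which attracts lymphocytes, by 1.81 ± 0.26 (3.51-fold, padj = 3.3e-06) and Tiparp by 1.28 ± 0.14 (padj = 3e-09; 3 arrays against 4). Cyp1b1 (1.04, padj = 0.024) and the quinone reductase Nqo1 (0.7, padj = 0.027) rose too, as did the interferon-induced Xaf1 (1.41, padj = 0.034), Lgals3bp (1.21, padj = 0.019) and Ifi27l2a (0.96, padj = 0.042). Of division genes, Ccnf fell by 1.02 (padj = 0.0094), Ube2c by 1.01 (padj = 0.00097), Pif1 by 0.82 (padj = 0.0042), Psrc1 by 0.82, the kinase Aurka by 0.78 (padj = 0.027) and the phosphatase Cdc25b by 0.72 (padj = 0.0044). Mt1 (0.82, padj = 0.4), Mt2 (0.44, padj = 0.66), Hmox1 (0.54, padj = 0.87) and Slc30a1 (-0.11) were not called. From 1 to 25 µg/mL Ccl20 rose by 1.72, 1.94, 1.86 and 1.81, and Tiparp by 1.21, 1.29, 1.32 and 1.28. The doses raised 3, 15, 25 and 28 genes and lowered 0, 8, 10 and 11, and at MP 1 the 3 were Ccl20, Tiparp and the homeobox gene Lhx4 (0.7). All 39 genes of MP 25 kept their sign within each of 2 slides. On the mean of the 55 genes called for NP or MP, the replicate 4 arrays at 1 µg/mL stood at 0.02 and 0.15 above medium and those of replicates 1 and 3 at 0.55 to 0.79. The total of 48 was 23 without medium replicate 1 or 4 of set A, 82 without the dim array (39 became 65 at MP 25), and 79 with slide as a fixed block.

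As lists at MP 25 and 2 h, 2 of 30 mitosis genes fell (7 over the list alone; median -0.4, padj = 2.9e-15, adjusted p = 0.2 with an estimated correlation). Lysosome genes had 5 rises over the list alone and 0 in the main test (0.27, padj = 7.1e-07, then 0.26), and inflammatory genes 1 (3 over the list alone, 0.24, padj = 0.017, then 0.36). NRF2 targets had 1 (0.11, padj = 0.0099, adjusted p = 0.6 with an estimated correlation). No member of 4 further lists was called: metal (0.15, padj = 0.023, then 0.2), copper (0.09, padj = 0.012, then 0.26), oxidative phosphorylation (0.1, padj = 0.0094, then 0.55) and p53 targets (-0.13, padj = 0.0021, then 0.036), each second value with an estimated correlation. NP 25 and MP 25 shared 5 rises and 4 falls (0.02 and 0 by independence). These comparisons share 4 medium arrays: the changes correlated at 0.71 over all genes, against 0.43 simulated for shared controls alone, 0.34 to 0.57 with the controls split, and the covariance was 0.022 against 0.01. At this dose and time NP and MP arrays with the same replicate number also deviated together (r 0.33 to 0.47), which none of these values takes into account.

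At 24 h MP 25 raised the chromatin remodelling gene Smarcd1 by 1 ± 0.21 and Baalc by 0.95, and lowered the serotonin receptor Htr7 by 1.05 and the carboxylesterase Ces2e by 0.99 (each padj = 0.04, 2 arrays against 4). MP 10 lowered Htr7 (-1.08, padj = 0.0051) and Ces2e (-0.9, padj = 0.016). Mt1 (0.6), Mt2 (0.45) and Hmox1 (0.38) had padj = 1 at MP 25, with Slc30a1 at -0.17. Hspa1a stood in the order of dose without being called (0.52, 1.01, 1.31 and 2.32, padj = 1, 1, 0.86 and 1). Its SE, 0.75 at MP 25, was 0.49 without the dim array, where MP 25 was called (padj = 0.027), and 0.26 without replicate 1 of MP 10 at 48 h as well, where MP 10 was too (padj = 0.0018). In limma 0 genes were called at MP 1 and MP 5 (257 and 425 at unadjusted p under 0.05). The total of 4 was 2 without replicate 1 of MP 25 and 7 without replicate 3. It was 2, 0, 2 and 2 without medium replicates 1 to 4 of set A, 7 without the dim array and 33 with the replicate block within the time. No list had a called member at MP 25. Camera called lysosome (0.27, padj = 6.3e-08, adjusted p = 0.2 with an estimated correlation), NRF2 (0.14, padj = 0.0021, then 0.53), immediate early (0.18, padj = 0.0031, then 0.54), matrix (0.12, padj = 0.0094, then 0.53), oxidative phosphorylation (0.07, padj = 0.0066, then 0.53) and p53 targets (-0.12, padj = 0.0024, then 0.036).

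At 48 h MP 25 raised Cyp1b1 by 1.27 ± 0.24 (padj = 0.0052), Vnn3, which recycles pantetheine, by 0.75 (padj = 0.031), the bile acid receptor Nr1h4 by 0.62 (padj = 0.021) and Halr1 by 0.59 (3 arrays against 4). Vav2, also called (1.22, padj = 0.05), was at -0.01 without replicate 2. MP 25 lowered Angptl7 (-1.1, padj = 0.023), Cadm4 (-1.06, padj = 0.031), Aoc3 (-0.79, padj = 0.0032), Id1 (-0.71, padj = 0.0019, but -0.55 and uncalled without replicate 3), Ndrg2 (-0.71, padj = 0.044) and the epoxide hydrolase Ephx2 (-0.67, padj = 0.0052). Mt2 was at 0 and Hmox1 at 0.82 (padj = 1), or -0.06 without medium replicate 1 of set A. MP 10 raised 8 genes, among them Hspa1a (2.89, padj = 0.042), the phosphatases of stress kinases Dusp1 (0.9) and Dusp6 (0.83) and the muscle stress gene Ankrd1 (1.18), and lowered 3. Without replicate 1 of MP 10 these became 1.16, 0.33, 0.25 and 0.43 (each padj = 1), and of the 11 genes 1 stayed called, Ephx2 (-0.76, padj = 0.02). Its replicate 1 correlated at -0.45 with the other arrays of its group and at 0.6 with NP 25 at 24 h. The split of MP 10 became 16 and 0 with the scanner's processed signals, 3 and 4 with scaling and 3 and 2 with the series matrix. That of MP 25, 5 and 6, became 3 and 2, 2 and 6, and 1 and 6, and 2 and 6 without background correction. MP 1 and MP 5 called 0 genes in limma (248 and 475 at unadjusted p under 0.05). At MP 25 camera called the integrated stress response (0.26, padj = 1.5e-06, adjusted p = 0.36 with an estimated correlation, 1 rise over the list alone) and p53 targets (0.16, padj = 0.00032, then 0.017). It also called NRF2 (0.11, padj = 0.01, then 0.6), ER chaperones (0.1, padj = 0.029, then 0.55), mitosis (0.15, padj = 0.031, then 0.82) and glycolysis (-0.07, padj = 0.007, then 0.31). The MP total of 19 was 3, 8 and 9 without medium replicate 1, 2 or 4 of set A, 11 without replicate 3 of MP 25, 10, 83 and 128 without replicates 1, 2 or 3 of MP 10, and 65 without the dim array (11 became 56 at MP 10 and 18 at MP 25). Within slides, 11, 11 and 10 of the 11 genes of MP 25 kept their sign. The MP 25 and NP 10 effects, with shared medium arrays, correlated at 0.19 (0.06 to 0.21 with the controls split), with covariance 0.026 against 0.01 simulated. The simulated r, 0.43 for shared controls alone, had no changed genes, and large NP effects lower r, so it cannot be compared.

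Nanoparticles and microparticles were compared directly at each matched dose. At 10 µg/mL and 24 h, NP exceeded MP in Hspa1a by 5.87 ± 0.7 (padj = 7e-10, 3 arrays against 3), Hspa1b by 5.84, Hmox1 by 3.97 ± 0.62 (padj = 9.4e-07), Nppb by 3.83, the protease Mmp10 by 3.26 and the arsenite-induced Zfand2a by 3.13. Metal genes were higher in NP: Mt2 by 2.8 ± 0.29 (padj = 7.9e-12), Mt1 by 2.53 (padj = 2.3e-07), Mtf1 by 0.74 and Slc30a1 by 0.69 (padj = 0.0016), with Slc39a10 lower (-1.32). Lower in NP were Il33 (-2.61), Nrep (-2.43), the chemokine Cxcl12 (-2.18), Gas1 (-2.09), Ppp2r2b (-1.99), Mxd3 (-1.98), Col3a1 (-1.62), Cenpa (-1.44) and Plk1 (-1.26). The oxidant and protein stress genes Sqstm1 (2.55), Srxn1 (2.42), Dnajb1 (2.51), Atf3 (2.84), Ppp1r15a (2.41) and Gdf15 (1.93) were higher. In limma at 24 h 0, 30, 762 and 1865 genes were higher in NP at 1, 5, 10 and 25 µg/mL and 0, 10, 567 and 1737 lower (376 at unadjusted p under 0.05 for 1 µg/mL), and the 40 at 5 µg/mL were 107 without the dim array. The NP 10 and MP 10 effects share medium arrays: they correlated at 0.39 (0.25 to 0.34 with the controls split). The covariance was 0.026 against 0.01 simulated, without regard to the replicate numbers (r 0.21 to 0.38). The simulated r of 0.43 again cannot be compared. With the scanner's processed signals the split at 10 µg/mL was 923 and 1077 (46.1% higher against 57.3), and at 25 µg/mL 2016 and 2858 (41.4% against 51.8), where the all-gene median shifted by -0.117. At 5 µg/mL the series matrix gave 24 and 13 (64.9% against 75).

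At 10 µg/mL and 24 h, 24 of 37 NRF2 targets were higher in NP (median 0.72, padj = 1e-16, and padj = 0.036 with an estimated correlation). So were 15 of 26 heat shock genes (0.69, padj = 5.2e-14, adjusted p = 0.11 with an estimated correlation), 18 of 26 immediate early genes (1.07, padj = 3.4e-13, then 0.067), 12 of 31 proteasome subunits (0.54, padj = 3.8e-10, then 0.3) and 12 of 32 lysosome genes (0.47, padj = 3.4e-06, then 0.29). Of 30 mitosis genes 15 were lower (-0.64, padj = 1.5e-09, then 0.35). Glycolysis genes were higher in 8 of 32 (0.38, padj = 0.00026, then 0.19), metal genes in 4 of 12 and lower in 1 (0.18, padj = 0.024, then 0.2), and the integrated stress response higher in 5 of 30 (0.22, padj = 0.0096, then 0.67). Matrix genes were lower in 6 of 29 and higher in 3 (-0.21, padj = 0.032, adjusted p = 0.6 with an estimated correlation). The p53 targets had 7 higher and 2 lower of 30 (3 lower over the list alone; padj = 0.28). Other members named by the rule include Insig1 (0.8), Adm (1.1), Ftl1 (1.37), Trf (-1.52), Neu1 (1.29) and Hopx (-1.48).

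At 10 µg/mL and 48 h, NP exceeded MP in Hspa1a by 5.57, Arc by 5.26, Nppb by 4.78, Atf3 by 4.29, Hmox1 by 3.32 (padj = 3.5e-06) and Mt2 by 0.97 (padj = 0.0029; 3 arrays against 3). Without replicate 1 of MP 10 the differences were 7.31 for Hspa1a and 4.11 for Hmox1. It was lower in Dcn (-5.14), Nrep (-5.13), Serpind1 (-4.66), Smtnl2 (-4.5) and the aryl hydrocarbon receptor gene Ahr itself (-4.41). At 48 h 1, 1415 and 2617 genes were higher in NP at 1, 5 and 10 µg/mL and 3, 1267 and 2626 lower, and within the 1 slide with both groups at 10 µg/mL, 5239 of 5243 kept their sign. The 4 at 1 µg/mL were Sh3d19 (0.72), Id1 (-0.69), Tmem132a (-0.76) and Aoc3 (-0.81), and 15 were called without the dim array. Of 30 mitosis genes 26 were higher in NP (1.4, padj = 3.8e-09, adjusted p = 0.36 with an estimated correlation), as were 28 of 32 replication genes (1.2, padj = 1.4e-07, then 0.43), 30 of 31 proteasome subunits (1.3, padj = 2.7e-13, then 0.2) and 24 of 30 in the integrated stress response (1.19, padj = 1.6e-08, then 0.29). NRF2 targets were higher in 27 of 37 and lower in 2 (1.39, padj = 1.6e-08, adjusted p = 0.2 with an estimated correlation), and matrix genes lower in 18 of 29 and higher in 8 (-0.78, padj = 0.0019, then 0.4). At 2 h 0, 0, 1 and 1 genes differed in limma (135, 209, 390 and 496 at unadjusted p under 0.05). They were Tiparp at 10 µg/mL (-0.83 ± 0.15, padj = 0.011) and Lhx4 at 25 (-0.67, padj = 0.00015), both lower in NP, and the total of 2 moved between 1 and 4 as single arrays were left out. With labels reassigned, 23 of 100 assignments gave as many at 2 h (highest 67), and 3 of 100 when reassigned within replicate numbers. At 24 h 30 did (highest 5053 against 3902), and 4 without the dim array (4687 against 4683). At 48 h only the real labels reached 5376 (next 5276).

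CuCl2 at 7 µg/mL lowered Ccl20 by 1.65 ± 0.28 (padj = 0.00085) and Tiparp by 0.83 ± 0.15 (padj = 0.005) at 2 h (3 arrays against 3), both of them genes that MP 25 raised. NaCl lowered the same genes (-1.66, padj = 0.00072, and -0.74, padj = 0.049), and CuCl2 against NaCl called 0 genes in limma (41 at unadjusted p under 0.05). Mt1 (-0.51) and Mt2 (-0.21) had padj = 1. The count of 2 for CuCl2 was 0 without its replicate 2, which lay on a particle slide, and 4 with the replicate block within the time. For NaCl the count of 2 was 1, 0 and 4 without its replicates 1, 2 or 3, 1 without medium replicate 2 of set B, and 6 with that block. At 24 h 0 genes were called in limma for CuCl2 (162 at unadjusted p under 0.05), NaCl (58) or one against the other (156), with Mt1 at -0.13, Mt2 at 0.12 and Hmox1 at 0.27 under CuCl2. Leaving out replicate 1, 2 or 3 of NaCl gave 1 gene for NaCl, and leaving out replicate 1 or 3 gave 1 for CuCl2 against NaCl. Camera called several lists. At 2 h these were cholesterol (0.11, padj = 3.8e-07, adjusted p = 0.22 with an estimated correlation), lysosome (-0.16, padj = 9.2e-06, then 0.31), immediate early (0.05, padj = 0.012, then 0.6) and p53 (0.06, padj = 0.048, then 0.2). At 24 h glycolysis (0.21, padj = 1.2e-10, then 0.0062) and p53 targets (0.11, padj = 0.0019, then 0.036) kept the call. The integrated stress response (0.18, padj = 7.4e-07, then 0.36), matrix (-0.13, padj = 3e-05, then 0.27), lysosome (-0.12, padj = 0.00077, then 0.43), immediate early (0.13, padj = 0.0092, then 0.6), cholesterol (0.07, padj = 0.011, then 0.59) and fibroblast lists (-0.12, padj = 0.04, then 0.31) did not.

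At 48 h CuCl2 raised 45 genes and lowered 36 (3 arrays against 3). The trypsin gene Try5 rose most (2.03 ± 0.17, padj = 8e-15; at least 3.75-fold, as medium was not above background), then the growth factor carrier Fgfbp1 (1.57, padj = 0.00032), the secreted carbonic anhydrase Car6 (1.57, padj = 8.1e-05), the stress gene Niban1 (1.51, padj = 0.024), Angptl6 (1.43, padj = 6.3e-05) and the peptide receptor Vipr2 (1.4, padj = 2e-08). Of the integrated stress response, Trib3 rose by 1.35 ± 0.3 (padj = 0.0056), Nupr1 by 1.31 (padj = 0.00038), Ddit3, which promotes cell death, by 1 (padj = 0.013) and Atf5 by 0.9 (padj = 0.00032). So did Gadd45a (0.94, padj = 0.00012), Klf4 (1, padj = 3.5e-05) and the ER oxidase gene Ero1a (0.64, padj = 0.00061). Id2 fell by 1.74 ± 0.26 (padj = 1e-05), the histidine lyase Hal by 1.45 (padj = 0.013), the peptide clearance receptor Npr3 by 1.13, Anp32a and the hyaluronidase Cemip by 1.06 each, Igf1 by 1.01 (padj = 0.0011), Id1 by 0.92 (padj = 1.7e-06), the collagen Col12a1 by 0.86 (padj = 0.016) and the copper-dependent Lox by 0.71 (padj = 0.0036). Mt1 (-0.37, padj = 0.88), Mt2 (-0.07, padj = 1), Slc30a1 (-0.26, padj = 0.72) and Hmox1 (1.65, padj = 0.27, and 0.49 without medium replicate 1 of set B) were not called. Of 30 genes in the integrated stress response 6 rose (9 over the list alone; 0.46, padj = 9.3e-19, adjusted p = 0.056 with an estimated correlation). Of 30 p53 targets 1 rose (3 over the list alone; 0.25, padj = 6.9e-09, then 1.8e-05), and of 29 matrix genes 1 fell (4 over the list alone; -0.29, padj = 3.8e-10, then 0.067, and 0.02 in that test with the replicate block). Camera also called NRF2 (0.18, padj = 4.2e-05, then 0.36), mitosis (0.25, padj = 1.4e-05, then 0.55) and oxidative phosphorylation (-0.08, padj = 0.024, then 0.6).

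Against NaCl at 48 h, CuCl2 raised 41 genes and lowered 13, with Trib3 at 1.33, Nupr1 at 1.46, Ddit3 at 0.96, Id1 at -0.87 and Id2 at -1.86, while NaCl against medium called 0 in limma (198 at unadjusted p under 0.05). All 81 genes of CuCl2 kept their sign within each of 3 slides, and 54, 53 and 54 of the 54 against NaCl did, on the same arrays that gave the calls. The 81 became 46 and 51 without CuCl2 replicate 1 or 2 and 53 without medium replicate 1 of set B, 122 without the dim array, and 129 with the replicate block within the time. The 54 became 32 and 30 without CuCl2 replicate 1 or 2, 34 and 30 without NaCl replicate 1 or 3, and 90 with that block. NaCl alone gave 2 without its replicate 1 or 3. With the scanner's processed signals CuCl2 had 45 rises and 19 falls (70.3% higher against 55.6). Over time, 5 genes had a higher CuCl2 effect at 48 than at 24 h, named after their values were seen: the proteases Try5 (1.87), Try4 (1.19) and Prss3 (1.03), Vipr2 (1.4) and the transcription factor Isx (1.14). CuCl2 and NP 5 at 48 h, each against the medium arrays of its own slides, shared 26 rises and 34 falls (4.94 and 3.26 by independence). CuCl2 and NP 10 shared 23 and 33 (9.69 and 7.08), with 4 rises of CuCl2 called in the opposite direction, and CuCl2 and MP 25 shared 1 and 4 (0.02 each). The values by independence assume separate medium cultures, which the labels do not state: at 48 h medium arrays with the same title in both sets correlated at 0.71, 0.32 and 0.32.

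The difference between the CuCl2 and NP 10 effects was tested at each time, with doses given as mass of compound and not of copper. At 2 h 6 genes differed, with Ccl20 (-3.07 ± 0.38, padj = 7.5e-08), Lgals3bp (-2, padj = 0.018) and Tiparp (-1.32, padj = 0.00013) lower under CuCl2. At 24 h 1091 differed, led by Hspa1a (-7.18 ± 0.96, padj = 1.1e-07), Hspa1b (-6.06, padj = 3.5e-07) and Hmox1 (-4.05, padj = 0.00057). At 48 h 5573 differed, led by Hspa1a (-8.05, padj = 6.4e-11), Hspa1b (-7.29, padj = 4e-11) and Arc (-7.14, padj = 3.9e-13). Against NP 5 the counts were 2, 63 and 2281. At 24 h the scanner's processed signals gave 632 higher and 616 lower for the NP 10 difference, against 439 and 652. The 6 at 2 h were 2 or 3 without any of CuCl2 replicates 1 and 2, replicate 3 of NP 10, medium replicate 4 of set A or replicates 2 and 3 of set B, and 52 or 61 with the replicate block, over all times or within the time. Against NP 5 the 2 were 55 or 71 with these blocks and 8 without the dim array. The 63 were 132 or 157 with the blocks, 141 without the dim array, 27 and 28 without CuCl2 replicate 1 or 2, 7 without NP 5 replicate 3, 29 and 27 without medium replicate 1 or 4 of set A, and 33 and 7 without replicate 2 or 3 of set B.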

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

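The tests of the difference between times, the 3 patterns weighed here, the tests on them and the reassignment of labels within replicate numbers were chosen only after the result was seen.

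Some values stood apart. In the 7 medium arrays at 2 h the heat shock list mean was 0.66 in replicate 3 of set B (nearest 0.72), and the ribosomal list mean was -0.17 in replicate 2 of set A (nearest -0.1). At 24 h the cholesterol list mean was 1.2 in replicate 4 of set A (nearest 1.32). These are 3 of 87 Dixon tests, which by chance alone would mark about 1 in 20. The effect differed between times for 1771 genes of NP 5 (48 against 24 h), 1512 of NP 10 (24 against 2 h), 3959 of NP 10 (48 against 24 h) and 5 of CuCl2 (48 against 24 h). Among probes without a gene name, left out of the other tests, 1913 changed at NP 10 and 48 h (1029 rose and 884 fell).

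The shift of particle arrays at 2 h on a mean of 55 genes was 0.67 ± 0.11 (SD, 22 arrays of replicates 1 to 3). The difference between 25 and 1 µg/mL was 0.03 (SE 0.02, 4 same-numbered pairs, NP and MP pooled). Large growth of this mean is excluded, slight growth or that of single genes is not. Mt1 at NP 1 and 25 was -0.82 and -0.11 (replicate 1), -0.15 and 0.26 (replicate 3). Medium replicates 1 to 3 differed from replicate 4 by 0.09 (SE 0.09) against 0.59 in the particle arrays, but replicate 4 of medium is 1 array, so a batch shared with the medium arrays of the same numbers stays open. The replicate 4 arrays at 1 µg/mL stood at 0.08, against 0.66 in replicates 1 and 3. The 55 genes were called on mostly replicates 1 to 3, which favours that gap, so it cannot decide. A difference between particle cultures other than dose, or saturation under 1 µg/mL with replicate 4 not exposed alike, stays open. A new culture series with several medium dishes per batch would part them.

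The library labelled NP 25 at 24 h replicate 1 and the library labelled MP 10 at 48 h replicate 1 lie far from their groups. In the latter, 118 genes at least 8-fold higher in NP stood at a median of 24.3% of the NP level (quartiles 20 and 30), which excludes a complete exchange of the samples. The 112 genes lower in NP stood at 30.6% of the way (22.7 to 38.2), and the likeness of these shares fits RNA of NP-exposed cells mixed into the sample. The correlation with NP 10 at 48 h minus that with NP 25 at 24 h was -0.09 (0.51 and 0.6), so a culture that responded as NP did stays open. The dim library correlated at 0.45 to 0.47 (5367 genes) with medium, MP, salts and NP 1 of 48 h and at -0.13 with its own group (0.9 to 0.94, highest MP, and -0.34 in the series matrix), and held 0.2% of the NP level over 44 genes, so a wrong label of that library, or a partial exchange with the MP sample, stays open.

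Mitosis genes were 1.79 higher (SE 0.16) at NP 10 and 48 h than in medium of that time, but in medium itself they fell by 3.28 (SE 0.14) from 24 to 48 h. Against medium of 24 h the NP cells stood at -1.49 (SE 0.09), which excludes an induction above the earlier level, and DNA replication gave 1.65 and -0.8. The NP cells thus kept part of a level that medium cells lost. Of 3572 genes outside these lists that changed in medium from 24 to 48 h, 86.3% lay on the 24 h side at NP 10, 77.4% at NP 5 and 52% at MP 25 (slope 0.83 at NP 10). Fewer cells per dish after NP exposure may have delayed the arrest of a crowded culture, and counting cells beside the arrays would test it.

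Group labels were reassigned among the same arrays, first without regard to the replicate numbers and then within them, since the numbers pair the salt arrays and several of the other comparisons. Chance was excluded both ways (number of assignments with as many genes, real value and highest other, then the highest within numbers, reached by the real labels alone) for NP over any dose at 24 h (1, 4420, 3526, then 4214) and 48 h (1, 5825, 5024, then 4590) and MP at 2 h (3, 48, 201, then 19). MP at 24 h (1, 4, 1, then 3), NP against MP at 48 h (1, 5376, 5276, then 5374) and CuCl2 minus NP 10 at 2 h (1, 6, 2, then 5) met the same rule, but within numbers by few genes. The pooled 5376 came mostly from 10 µg/mL (5243 genes). Assignments that change only 1 µg/mL (4 genes) can leave it nearly unchanged, so the test speaks to the pooled count and not to each dose. For NP against MP at 24 h with the dim array out, 4 assignments made without regard to the numbers reached the real count (4683, highest other 4687). Within numbers (highest other 4682) the labels at 25 µg/mL, which gave 4605 genes, could not change. The groups of that dose share 1 number and are of equal size, so the test within numbers cannot decide.

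For CuCl2 minus NP 10 at 48 h (3, 5573 and 5746) and CuCl2 minus NP 5 at 2 h (3, 2 and 2), 24 h (3, 63 and 95) and 48 h (3, 2281 and 2933), chance was excluded without regard to the numbers but not within them. There 4, 4, 2 and 4 of 32 assignments reached the real count, with 5745, 6, 63 and 2832 as the highest other. It was not excluded either way for MP at 48 h (7, 19 and 100), NP against MP at 24 h with all arrays (30, 3902 and 5053) or CuCl2 minus NP 10 at 24 h (6, 1091 and 1813). Within numbers these gave 10 of 100 (43), 6 of 100 (4240) and 4 of 32 (1472). For NP at 2 h (8, 18 and 126) and NP against MP at 2 h (23, 2 and 67) chance was not excluded at first, while within numbers 1 of 100 (14) and 3 of 100 (2) did, so the answer depends on the pairing. Assignments that call many more genes than the real one point to a structure of the samples.

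Among the 35 ways to split 3 particle and 4 medium arrays, only the real one (1) gave as many genes for MP 5, 10 and 25 at 2 h (23 and 3, 35 and 3, 39 and 6) and MP 25 at 48 h (11 and 3). The same held for NP 5, 10 and 25 at 2 h (2 and 1, 3 and 2, 16 and 1) and at 24 h (239 and 115, 1671 and 880, 4093 and 3185), and for NP 5 and 10 at 48 h (2777 and 1837, 5711 and 4329). Chance was not excluded, with 2 splits, for MP 1 at 2 h (3 and 3), MP 10 at 48 h (11 and 63), NP 1 at 2 h (2 and 3), NP 1 at 24 h (1 and 1) and NP 1 at 48 h (33 and 152), nor, with 35 splits and 0 genes real or other, for MP 1 and MP 5 at 24 and 48 h. For NP 1 at 2 and 48 h same-numbered arrays deviated together, and among the 8 splits that part all 3 pairs the highest other gave 1 and 2. The same pairing holds for MP 10 at 24 h, where only the real split of the 35 (1) gave 2 genes and the highest of those 8 gave 1. The 152 came from a split with both arrays of replicate 1 on one side and both of replicate 4 on the other, so it follows the replicate number, and 8 splits are too few for a share under 0.05.

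With 3 arrays against 3 the 10 splits are too few for a share under 0.05. The numbers of splits with as many calls, then the real value and highest other, were as follows. CuCl2 against medium gave 1 (2 and 0) at 2 h, 10 (0 and 0) at 24 h and 1 (81 and 3) at 48 h. CuCl2 against NaCl gave 10 (0 and 0), 10 (0 and 0) and 1 (54 and 3). NaCl against medium gave 1 (2 and 0), 10 (0 and 0) and 10 (0 and 1). NP against MP at 1 µg/mL gave 10 (0 and 54), 10 (0 and 0) and 2 (4 and 12), at 5 µg/mL 10 (0 and 1), 1 (40 and 0) and 1 (2682 and 295), and at 10 µg/mL 1 (1 and 0), 1 (1329 and 0) and 1 (5243 and 2459). At 25 µg/mL and 2 h it gave 1 (1 and 0). The 54 and 12 at 1 µg/mL came from splits with both arrays of replicate 4 on one side, and the splits that part all 3 pairs gave 0 at most.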

How the results depend on the processing

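The settings with the dim array or 1 further array left out, with same-title medium arrays averaged and with the replicate block within each time, and the tests on them, were chosen only after the result was seen. With 3 arrays in most groups precision is limited, and 42.1 to 53.5% of probes above background leaves genes expressed at low level untested. Where a gene was above background in 1 group alone, its fold is inexact, and "at least" marks a lower bound. A change of setting that moved a count is given below, and the cause was not tested. The values to compare are 18 genes for NP, 48 for MP, 2 each for CuCl2, NaCl and NP against MP, 2 for CuCl2 minus NP 5 and 6 for CuCl2 minus NP 10 at 2 h. They are 4420 for NP, 4 for MP, 3902 for NP against MP and 63 for CuCl2 minus NP 5 at 24 h. At 48 h they are 5825 for NP, 19 for MP, 81 for CuCl2, 0 for NaCl, 54 for CuCl2 against NaCl, 5376 for NP against MP and 2281 for CuCl2 minus NP 5.

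Without background correction MP at 24 h gave 2. The scanner's processed signals gave 56 for NP, 0 for CuCl2, 1 for NaCl and 6 for CuCl2 minus NP 5 at 2 h, and 1 for MP at 24 h. Scaling between arrays gave 38 for NP and 1 each for CuCl2, NaCl and NP against MP at 2 h, and 12 for MP at 48 h. The series matrix gave 1 for NaCl at 2 h, 2 for MP at 24 h and 10 for MP at 48 h. Without the filter on dim probes NP had 7 and NaCl 1 at 2 h, and MP 9 at 24 h. With signal above background asked of at least 50% of all arrays, NP against MP gave 1 at 2 h and MP 8 at 48 h. The mean of a gene's probes gave 9 for NP at 2 h. By adjusted p alone the counts were 30 for NP and 101 for MP at 2 h, 8773 for NP and 7212 for NP against MP at 24 h, and at 48 h 9776 for NP, 30 for MP, 131 for CuCl2, 9257 for NP against MP and 3583 for CuCl2 minus NP 5.

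Slide as a fixed block gave 28 for NP, 79 for MP and 4 for CuCl2 minus NP 5 at 2 h. As a random block (correlation 0.209) it gave 55 for NP, 86 for MP, 16 and 12 for CuCl2 minus NP 5 and NP 10 at 2 h, 102 for CuCl2 minus NP 5 at 24 h, and 122 for CuCl2 and 1 for NaCl at 48 h. No comparison lost its calls under a slide block. With the medium arrays of both sets together the counts were 75 for NP, 4 for CuCl2, 144 and 112 for CuCl2 minus NP 5 and NP 10 at 2 h, 8 for MP and 267 for CuCl2 minus NP 5 at 24 h, and 37 for MP, 137 for CuCl2 and 1 for NaCl at 48 h. With same-title medium averaged they were 6 for NP, 30 for MP, 119 and 94 for CuCl2 minus NP 5 and NP 10 at 2 h, and 2 for MP and 251 for CuCl2 minus NP 5 at 24 h. Medium of set A against set B called 0 genes in limma at each time (318, 63 and 121 at unadjusted p under 0.05).

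The replicate block gave 61 for NP, 55 and 52 for CuCl2 minus NP 5 and NP 10 at 2 h, and 132 for CuCl2 minus NP 5 at 24 h. Within each time the block gave 57 for NP, 4 for CuCl2, 6 for NaCl, 71 and 61 for CuCl2 minus NP 5 and NP 10 at 2 h, 33 for MP and 157 for CuCl2 minus NP 5 at 24 h, and 129 for CuCl2 and 90 for CuCl2 against NaCl at 48 h. It ended the calls of no comparison. Of the 460 values of named genes, the block over all times weakened 5 and made 2 called, and within each time it weakened 9 and made 2 called. Of 300 list tests, the block over all times ended 3 calls and added 6. In comparisons of particles with medium the arrays share a number, and pairing was met in 1 of 4 for NP and 0 of 4 for MP at 2 h, 0 of 4 for NP and 2 of 3 for MP at 24 h, and 1 of 3 for NP and 1 of 4 for MP at 48 h. For NP against MP it was met in 2 of 3 at 24 h and 2 of 3 at 48 h. Of the arrays, 7 of 12 for NP and 5 of 12 for MP at 2 h correlated best with their own number.

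The arrays of a time alone gave 75 for MP, 0 each for CuCl2, NaCl and NP against MP and 7 for CuCl2 minus NP 5 at 2 h, 0 for MP and 38 for CuCl2 minus NP 5 at 24 h, and 1 for MP at 48 h. Array weights gave 167 for NP, 181 for MP, 5 for CuCl2, 6 for NaCl, 9 for NP against MP, 155 and 123 for CuCl2 minus NP 5 and NP 10 at 2 h. They gave 47 for MP and 321 for CuCl2 minus NP 5 at 24 h, and 176 for CuCl2, 1 for NaCl and 139 for CuCl2 against NaCl at 48 h. With the dim array out the counts were 62 for NP, 82 for MP and 8 for CuCl2 minus NP 5 at 2 h, 7 for MP and 141 for CuCl2 minus NP 5 at 24 h, and 65 for MP, 122 for CuCl2 and 79 for CuCl2 against NaCl at 48 h, and 1443 for CuCl2 minus NP 10 at 24 h. With replicate 1 of MP 10 at 48 h out as well they were 72, 89 and 8 at 2 h, 7 and 166 at 24 h, and 131 for CuCl2 and 84 for CuCl2 against NaCl at 48 h.

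Of 85 list tests called, 8 held with an estimated correlation, 49 with fry, 82 with the replicate block and 81 with the dim array out. Of 460 values of named genes, 337 kept their label under every setting. The series matrix weakened 49 and reversed 5, the arrays of a time alone weakened 42, and the scanner's processed signals 35. At NP 25 and 24 h Prnp went from -0.6 to 0.27 (series matrix), 0.01 (array weights) and 0.11 (dim array out, alone or with the other). Egln3 went from 1.31 to -0.19, -0.2 and -0.24, and Slc16a3 from 1.27 to -0.11, -0.01 and -0.1. List medians near 0 changed sign. At NP 25 and 24 h the scanner's processed signals gave -0.1 for the integrated stress response and -0.07 for iron handling. The series matrix gave -0.52 for the former, 0.05 for copper, -0.12 for inflammatory genes, -0.03 for epithelial and -0.66 for club and ciliated markers. It gave -0.18 for oxidative phosphorylation at NP 10 and 48 h and -0.17 against MP. Lipoylation genes at NP 10 and 48 h had -0.02 and -0.08 with these sources, and p53 targets between NP and MP at 24 h -0.02 and -0.01. With the series matrix Krt19 went from 2.72 to -0.03 and Tubb4b from 0.6 to -0.66.

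Leaving out in turn each array of the groups compared gave these ranges, while the dim array, given above, moved comparisons that it is not part of. At 2 h they were 2 to 48 for NP, 23 to 59 for MP, 0 to 3 for CuCl2, 0 to 4 for NaCl, 0 to 0 for CuCl2 against NaCl, 1 to 4 for NP against MP, and 2 to 4 and 2 to 8 for CuCl2 minus NP 5 and NP 10. At 24 h they were 4373 to 5035 for NP, 0 to 7 for MP, 0 to 0 for CuCl2, 0 to 1 for NaCl and for CuCl2 against NaCl, 3760 to 4683 for NP against MP, and 7 to 75 and 816 to 1050 for CuCl2 minus NP 5 and NP 10. At 48 h they were 5712 to 6203 for NP, 3 to 128 for MP, 46 to 83 for CuCl2, 0 to 2 for NaCl, 30 to 59 for CuCl2 against NaCl, 5078 to 5795 for NP against MP, and 1727 to 2893 and 5476 to 5863 for CuCl2 minus NP 5 and NP 10. Of 3058 values of named genes, 2777 kept their label, 274 weakened, 3 became called and 4 reversed: Vav2 at MP 25 and 48 h (1.22 to -0.01 without replicate 2) and the 3 genes above without the dim array. Without another array they moved the other way: Prnp to -1.05 and Egln3 to 2.11 without replicate 3 of NP 25, and Vav2 to 1.9 without replicate 1 of MP 25. Without any 1 of MP 10 replicates 1 and 3 or MP 25 replicate 3 at 2 h, NP 10 replicates 1 and 3 or NP 25 replicate 3, NP against MP gave 1, and without MP 5 replicate 2 or 3 or NP 1 replicate 4 it gave 4. CuCl2 minus NP 5 gave 4 at 2 h without CuCl2 replicate 1 or medium replicate 3 of set B.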

Other observations

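The genes and groups described here, and the tests on them, were chosen only after the result was seen.

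The NP 10 effects on several programmes differed between 24 and 48 h. Of 30 mitosis genes 29 had a higher effect at 48 h (median difference 2.4), with 27 of 32 in DNA replication (1.36), 25 of 30 in the integrated stress response (1.38) and 24 of 31 proteasome subunits (1). Effects on lysosome genes went the other way, with 9 of 32 lower at 48 h and 2 higher, and so did those on matrix genes (16 of 29 lower, 5 higher) and fibroblast markers (4 of 9 lower, 1 higher). These are differences from medium, which itself moved. In the NP 10 cells the mitosis mean went from -0.5 to -1.32 (medium 0.16 to -3.11), DNA replication from 0.09 to -0.96 (medium -0.16 to -2.61) and lysosome from 0.33 to 0.9 (medium -0.4 to 0.43), so their levels ran opposite to their effects. The integrated stress response mean went from 0.53 to 0.68 while medium fell from 0.21 to -0.97, which made up most of the difference. Levels and effects went the same way for the proteasome (1.03 to 1.53, medium 0.48 to 0.12) and the matrix (0.61 to 0.23, medium 0.66 to 0.82). The effect on Mt2 went from 3.16 to 1.32 (NP 10 3.08 to 2.28, medium -0.08 to 0.96) and that on Hspa1a from 7.17 to 8.46.

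At 24 h NP 5 already raised 14 of 32 lysosome genes (median 0.59) and 8 of 37 NRF2 targets (0.38) and 3 of 26 heat shock genes, and lowered 2 of 30 mitosis genes. Without the dim array these were 16, 11, 6 and 6. NP 10 raised 20 of the lysosome genes (0.74) and 26 NRF2 targets (0.79), and lowered 18 mitosis genes (-0.75). Id1, which holds back differentiation, fell at 48 h under NP 1, 5 and 10 (-0.77, -1.69 and -2.09), MP 25 (-0.71, and -0.55 and uncalled without its replicate 3) and CuCl2 (-0.92), while MP 1, 5 and 10 (-0.08, -0.34 and -0.53) were not called. Lox, which needs copper as its cofactor, fell under NP 10 (-1.42) and CuCl2 (-0.71).

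CuCl2 left Mt1 and Mt2 uncalled at each time, while its 81 genes at 48 h overlapped those of NP 5 (26 of 45 rises and 34 of 36 falls) and of NP 10 (23 rises and 33 falls, with 4 rises opposite). The metallothionein rise may therefore need copper delivered by nanoparticles, or a salt response between the times sampled may have been missed. The CuCl2 count at 48 h ran from 46 without its replicate 1 to 176 with array weights, and noise shared through medium may add to the overlap, as medium arrays with the same title in both sets correlated at up to 0.71. Measuring Mt1 at several salt doses between 2 and 24 h would separate these.

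CuCl2 and NaCl both lowered Ccl20 and Tiparp at 2 h against the same medium, so a need for copper stays open. In that medium mean Ccl20 was 4.22 (set A 3.57) and Tiparp 0.18 (0.26). CuCl2 called 4 genes against both sets, and 0 with that time's arrays alone. Each MP dose raised both genes, and NP raised Ccl20 at 1 and 10 µg/mL and Tiparp at 1, 5 and 25. What links the opposite directions, or how salt dishes were handled, was not tested.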
